A study of Mus musculus with 10 samples.

How the data were processed

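Nuclei of wild-type mouse hippocampus were profiled in 10 samples, which the labels place in 1 group. Per the labels' protocols, nuclei were isolated from frozen tissue, stained with the DNA dye 7AAD, sorted as single nuclei, and loaded at about 5000 per sample. Libraries were made with 10x Genomics droplet chemistry that reads the 3' ends of transcripts, and were sequenced to more than 50000 reads per nucleus. Cell Ranger 4.0.0 is named in the matrix header and in the submitters' processing notes, which also name the builds mm10 and GRCm38. Whether intronic reads were counted, which annotation release was used and whether the barcodes were filtered further are not given in the sources used here.

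The deposited matrix holds UMI counts per gene and barcode with no scaling, per the file headers and as checked on its 35783047 nonzero entries, all of which were whole numbers of at most 1334. Of its 24837 genes, 5612 had no UMI. The deposited barcode and gene lists hold names and no measurement. The barcodes carry suffixes 1 to 7 for 10 samples, and no label ties a suffix to a sample. All nuclei were therefore 1 sample. Nuclei are not replicates, so no p-value, standard error or count of changed genes was computed, and values of single barcode sets describe those sets alone. Gene coordinates come from GENCODE M21 on GRCm38, to which 24715 of the 24837 gene identifiers matched.

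Before the data were examined, the comparisons, the gene lists, the cell type markers, the rule for named genes and most alternatives were fixed. Nuclei were kept with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs, which removed 108 of 15661 barcodes. Doublets were called per barcode set with the Scrublet method in scanpy 1.11.5 (expected rate 0.05), and 299 of 15553 nuclei (1.92%) were removed. In sets 5 and 7 the share called was under 0.5% (0.405 and 0.450%), and the caller is not taken to have worked there. Its 9 and 3 calls in those sets are among the 299 removed, although the plan left the caller out of use under 0.5%. Clusters that mix markers of several classes remained and were left unnamed.

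Genes outside the lists and markers were split at random, with a fixed seed, into 12216 genes allowed in clustering and 12200 held-out genes. All genes of the preset lists were kept out of clustering. Up to 2000 variable genes and the markers, 2173 features in all, were scaled to 10000 UMIs per nucleus and log-transformed. The first 30 principal components, a graph of 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 gave 44 clusters. No integration across barcode sets was used, and many clusters held mostly nuclei of set 1, of sets 2 to 4, or of sets 5 and 6.

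Clusters were named from the markers of 21 cell types. A marker counted as high in a cluster when its level was at least 0.25 of its highest level in any cluster and at least 5% of the nuclei had a UMI. A name needed at least 3 high markers. A cluster stayed unnamed when at least 3 markers, and at least 0.5 of all markers, of another class were raised 2-fold, or when its 10 leading genes held more markers of another class. It also stayed unnamed when its median UMIs, relative to its barcode sets, were under 1 part in 3 of the typical nucleus and no marker of the class was among those leading genes. Leading genes were ranked by fold over all other nuclei, with 5 CPM added to both, among genes seen in at least 10% of the cluster's nuclei. The markers were fixed beforehand, but this rule was built over several rounds while looking at the clusters. The added 5 CPM were chosen over 1 after 1, 5, 10 and 20 had been tried, and before any value of a comparison was computed. The rule left 10 clusters with 1791 of 15254 nuclei unnamed. Pericytes, endothelial cells and fibroblasts were joined as vascular cells.

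For each comparison, UMIs of a gene were summed over the nuclei of each side and divided by the total UMIs of that side, giving UMIs per 1000000 UMIs, called CPM. The ratio of the 2 sides has an exact 95% interval for a pair of Poisson counts, shares of nuclei have an exact binomial (Clopper-Pearson) interval, and both cover counting error only. Where a side had no UMI, its fold was set against 3 UMIs. A list is described by the median log2 ratio of its members with at least 100 UMIs over both sides, and by the percentile of that median among 10000 random lists of the same size matched on UMIs in 20 bins. A percentile under 2.5 or over 97.5 is outside the central 95%. This percentile describes these libraries and is not a test across animals. Counts of members at least 2-fold higher or lower describe size alone. The 15 lists cover H3K4 methyltransferases, COMPASS subunits, H3K4 demethylases, other chromatin regulators, plasticity and learning genes, immediate early genes, glutamate receptors, GABA receptors, voltage-gated channels, synaptic vesicle release, cholesterol biosynthesis, glycolysis, stress and heat shock, sex-linked genes and haemoglobin, and 2 members of the sex-linked list, Xist and Tsix, were not in the gene list used here.

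Genes named in the text follow a fixed rule. It takes every H3K4 methyltransferase, the 2 highest and 2 lowest members of each list with 5 or more measured members, and in each comparison the 8 highest and 8 lowest held-out genes. Held-out genes needed at least 500 UMIs over both sides, the same direction in every barcode set with at least 50 nuclei on both sides, no place in a list or among the markers, and a gene name that is not provisional or mitochondrial. The text names part of the list members and held-out genes this rule takes, and some are not reported here. Held-out genes took no part in clustering, although the leading genes used to name clusters were ranked over all genes. Shares of nuclei with a UMI are also given with every nucleus thinned to 1000 UMIs.

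The code for ratios and lists were tested on counts simulated from the real sums, with 200 genes changed. Of genes changed 2-fold, 91% were recovered with their direction for neurons against non-neuronal nuclei (13509 genes), 97% for excitatory against inhibitory neurons (13053 genes) and 97% for granule against CA neurons (11897 genes). Of genes changed 4-fold, 98, 100 and 100% were recovered. The intervals held the true ratio for 95.8, 95.5 and 95.5% of genes, and 5, 4 and 5 of 100 unchanged lists fell outside the central 95%. Counts were drawn from the Poisson distribution that the intervals assume. Their coverage therefore says nothing of spread between nuclei or barcode sets. Clustering and naming were tested on simulated nuclei of known class. A first simulation with fewer nuclei per class and without Cajal-Retzius cells left astrocytes and part of the inhibitory neurons unnamed. A second, with every class of at least 100 nuclei except excitatory neurons of no named subtype, gave the right name to 100% of 2635 nuclei. The same simulation without Cajal-Retzius cells gave it to 88.9% of 2528 nuclei and left 11.1% unnamed, so naming depends on which classes are present. Both drew nuclei from the pooled sums of each class, so spread within a class or between barcode sets was not simulated.

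Alternatives fixed beforehand were other scalings (nuclei weighted equally, means per nucleus without scaling, thinning to 1000 UMIs), a minimum of 1000 UMIs or no filter, doublets kept, resolutions of 0.5 and 2, clustering features centred within barcode sets, each barcode set left out in turn, and list minimums of 20 and 500 UMIs. Added after seeing the data were leading genes ranked with 1, 10 or 20 CPM, unnamed clusters put in their best class, the median over barcode sets, random lists also matched on gene length, and every alternative for the held-out genes. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.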

Results

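Single-nucleus RNA sequencing was done on the hippocampus of wild-type C57B/6J mice aged 4 to 7 months that had received no stimulation. The labels give 10 samples, all of 1 group. The titles of 4 call them RNASET2 controls, while all characteristics are the same as in the other 6. Nuclei were deposited together as 1 matrix of 24837 genes and 15661 barcodes, which held 101300889 unique molecular identifiers (UMIs, each standing for 1 captured transcript molecule). The barcodes carry 7 suffixes, called barcode sets here, and no label ties a set to a sample. Whether the matrix holds nuclei of all 10 samples is thus not known. The data were therefore treated as 1 sample with no replicates. No p-value was computed, and every 95% interval covers counting error only. Total UMIs per set were 19789220, 26207554, 21766297, 18900157, 6996728, 6335095 and 1305838 in sets 1 to 7. Median UMIs per barcode were 5477, 8052, 8176, 7605, 2822, 2413 and 1012. The series title concerns SETD1B, an enzyme that methylates lysine 4 of histone H3 (H3K4), in learning and neuronal plasticity genes. The comparisons below ask in which hippocampal cell classes its gene, the related enzymes and plasticity genes were transcribed.

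Neurons made up most of the nuclei. Of 15254 nuclei used, 9920 were neuron-like (65.0%, exact binomial interval 64.3 to 65.8), and 3436 were like non-neuronal cells (22.5%, 21.9 to 23.2). All classes were named from marker genes alone, so each name below stands for nuclei like that type. CA1 pyramidal neurons, the output neurons of the hippocampus proper, were 2720 nuclei (17.8%, 17.2 to 18.4), and CA2/CA3 pyramidal neurons were 1044 (6.84%). Dentate granule neurons, which receive the main cortical input, were 2421 nuclei (15.9%, 15.3 to 16.5). Subicular or cortical pyramidal neurons numbered 1870 (12.3%) and inhibitory neurons 1542 (10.1%, 9.63 to 10.6). Mossy cells, excitatory neurons of the dentate hilus, were rare at 42 nuclei (0.275%), as were Cajal-Retzius cells at 107 (0.701%), which were counted with neither side. Oligodendrocytes, the myelinating cells, were the most numerous non-neuronal class at 2565 nuclei (16.8%, 16.2 to 17.4). They were followed by microglia at 385 (2.52%), oligodendrocyte precursors at 327 (2.14%), astrocytes at 128 (0.839%) and vascular cells at 31 (0.203%). A further 1791 nuclei (11.7%) were left unnamed.

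These shares differed widely between barcode sets. Neurons were 38.7, 69.2, 68.0, 58.9, 80.7 and 99.8% of sets 1 to 6 and 0.151% of set 7, and non-neuronal nuclei were 0.0434% of set 6. Unnamed nuclei were 30.03% of set 1 and 23.2% of set 7. In set 1 they included 705 nuclei of 1 cluster, with a median of 6962 UMIs, and 140 of another, with a median of 8349.5. Whether these are neurons was not tested, so the neuron share of set 1 could be higher. Per the labels' protocols, nuclei were sorted on the DNA dye 7AAD before loading, and barcodes under 500 UMIs were left out here, so the shares describe the nuclei that passed both.

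**Figure D1:**
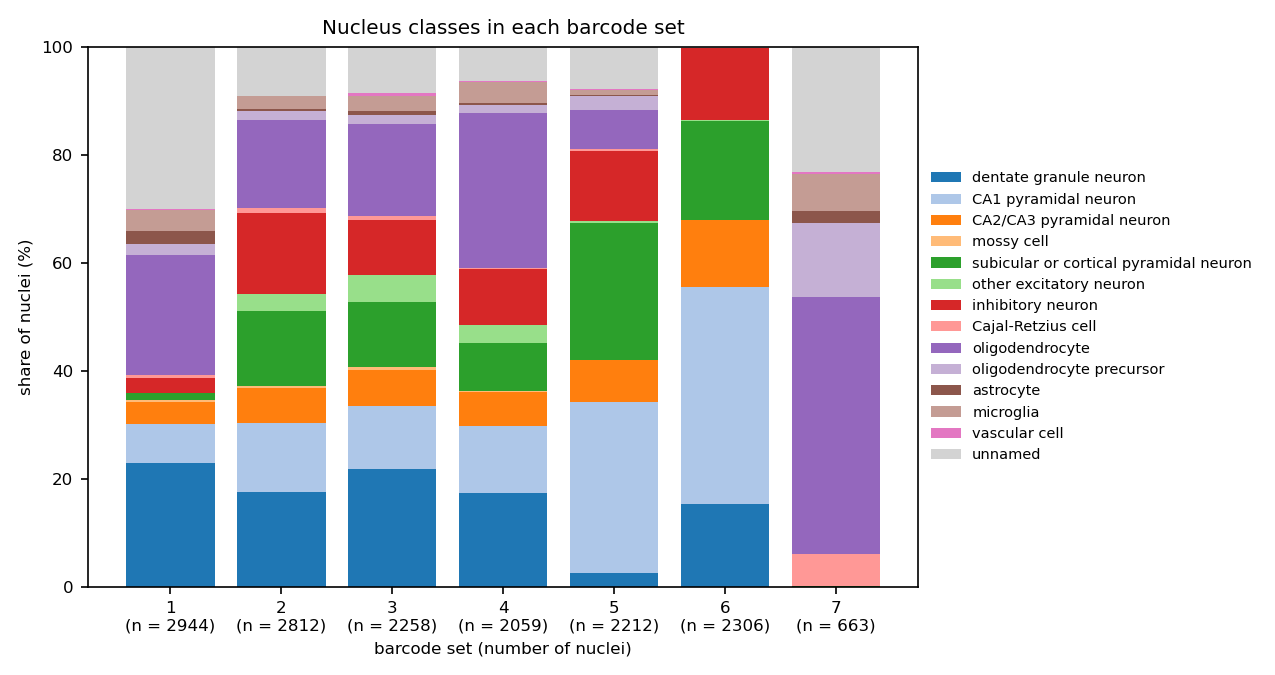
Stacked bars give the share of nuclei (percent, vertical axis) of each marker-named class in each of the 7 barcode sets (horizontal axis, number of nuclei in brackets), with unnamed nuclei in grey. Neurons fill 99.8% of set 6 and 0.151% of set 7, and oligodendrocytes 47.7% of set 7.

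The first comparison asked where the H3K4 methyltransferases and plasticity genes were transcribed, in neurons or in other cells. Relative to total UMIs, Setd1b was lower in neurons, at 17.8 UMIs per 1000000 UMIs (counts scaled this way are called CPM, 16.8 to 18.8, from 1339 UMIs) against 26.6 in non-neuronal nuclei (22.8 to 30.8, from 176 UMIs), a ratio of 0.669 (0.572 to 0.788), although per nucleus without scaling it was higher in neurons (log2 ratio 1.40). Kmt2c, which encodes a related H3K4 methyltransferase, was also lower in CPM, at 233 against 393 (ratio 0.592, 0.5681 to 0.617), and higher per nucleus (log2 ratio 1.22). Both ratios of CPM were below 1 in 5 of 5 barcode sets with at least 50 nuclei on each side. Genes of plasticity and learning stood far higher in neurons, with a median log2 ratio of 2.89, above all of 10000 random lists matched on UMIs (percentile 100).

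Neurons held 3.94 times as many UMIs per nucleus as non-neuronal nuclei (mean 7590 against 1928). Without scaling, the median log2 ratio of 13509 genes was 1.74 instead of -0.24, and the log2 ratio of Setd1b relative to that median was -0.34, the same on both scales by construction, and -0.14 with thinning. Among the other methyltransferase genes, Kmt2a was slightly higher in neurons (ratio 1.18, 1.11 to 1.24, in 4 of 5 sets). Kmt2b (0.869, 0.756 to 1.003), Setd1a (1.19, 0.922 to 1.55) and Kmt2d (1.04, 0.907 to 1.19) were not separable at this depth. By class, Setd1b was at 26.4 CPM in oligodendrocytes (22.0 to 31.5) and 38.9 in microglia (24.7 to 58.4, from 23 UMIs), and at 16.9 in CA1 (15.01 to 18.9) and 19.3 in CA2/CA3 neurons (16.9 to 22.0). Oligodendrocyte precursors were at 18.1 (10.4 to 29.4, from 16 UMIs). A Setd1b UMI was seen in 12.1% of neurons and 4.77% of non-neuronal nuclei. With every nucleus thinned to 1000 UMIs the shares were 1.95% and 2.48%, which left out 29 and 736 shallower nuclei. As a measure of free RNA, Slc17a7, the vesicular glutamate transporter of excitatory neurons, had a UMI in 2.52% of thinned oligodendrocytes against 20.4% of thinned excitatory neurons (4.64% and 66.0% unthinned, median depths 1689 and 5562.5 UMIs). These shares alone do not set Setd1b apart from free RNA, so its CPM are read here. On that scale Slc17a7 was at 25.4 in oligodendrocytes against 232 in excitatory neurons, whereas Setd1b in oligodendrocytes exceeded its level in neurons.

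The Setd1b gene (ENSMUSG00000038384) lies on chromosome 5 from 123142193 to 123168629 on the plus strand, in coordinates of GRCm38 with the GENCODE M21 annotation, and Gm26745 overlaps it on the other strand. Kmt2c (ENSMUSG00000038056) lies on the minus strand of chromosome 5 from 25271798 to 25498783, and Kmt2a (ENSMUSG00000002028) on that of chromosome 9 from 44803355 to 44881296. Kmt2b (ENSMUSG00000006307) spans 30568858 to 30588726 of chromosome 7, Kmt2d (ENSMUSG00000048154) spans 98831669 to 98871204 of chromosome 15, and Setd1a (ENSMUSG00000042308) spans 127776670 to 127800122 of chromosome 7. Setd1a shares its strand with the overlapping Gm49388, Kmt2a with Gm48314 and Kmt2c with Gm20432, so reads in the overlaps could be split and their levels are uncertain to that extent. The values are counts over whole genes, with no exon or UTR resolved.

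**Figure D2:**
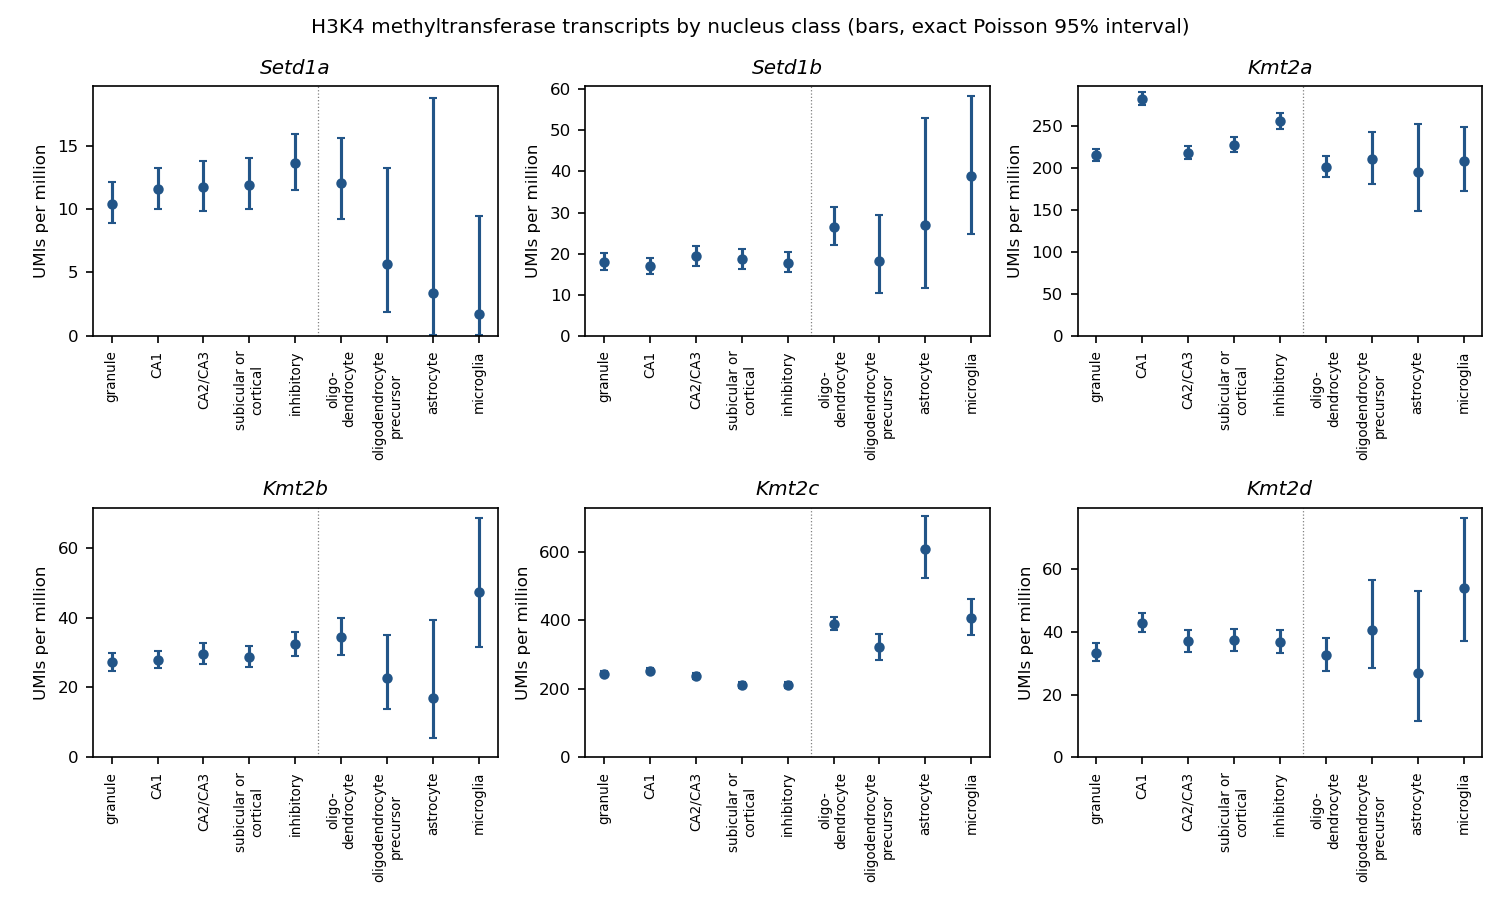
Points give CPM (vertical axes, each from 0) of the 6 H3K4 methyltransferase genes in 9 nucleus classes (horizontal axes), with bars for the exact Poisson 95% interval and a dotted line between neurons (left) and other cells (right). Setd1b is at 16.9 to 19.3 in the 5 neuronal classes and at 26.4 in oligodendrocytes, and Kmt2c is higher in each of the 4 non-neuronal classes, an order that holds in CPM and turns per nucleus for neurons against non-neuronal nuclei as a whole.

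Of 37 plasticity and learning genes, 33 were at least 2-fold higher in neurons and 1 was at least 2-fold lower. Grin2a, an NMDA receptor subunit, was 31.2-fold higher and Camk2a, a calcium-dependent kinase of the synapse, 23.7-fold higher. Creb1, a transcription factor of memory formation, was at a CPM ratio of 0.451 and above 1 per nucleus (log2 0.83), and so was Cdk5 (0.538, and log2 1.08 per nucleus). Of the 4 lists of synaptic and channel genes, 3 stood above the central 95% of random lists. GABA receptor genes had a median log2 ratio of 3.28 (percentile 100), with 12 of 14 at least 2-fold higher, such as Gabra5 (14.1-fold). Voltage-gated channel genes were at 2.69 (percentile 100), with 25 of 29 at least 2-fold higher. Among them Kcna1, a potassium channel, was 5.06-fold lower. Synaptic vesicle release genes were at 2.21 (percentile 99.9), with 15 of 17 at least 2-fold higher, including the calcium sensor Syt1 (24.3-fold) and Unc13a (14.1-fold). Glutamate receptor genes were at 1.78, which was at percentile 97.2 and thus within the central 95% of random lists, and Grm3 was 12.1-fold lower. Immediate early genes, which neuronal activity induces, were at 1.18 (percentile 99.99), with 10 of 18 at least 2-fold higher, led by Npas4 (8.93-fold, from 6 UMIs on the non-neuronal side) and Nr4a3 (7.65-fold).

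Of 13 lists with a percentile, stress and heat shock genes were the only 1 with a median below the central 95% of random lists in neurons (-1.55, percentile 0.43), and their median turned to 0.43 per nucleus. Ddit4, which stress induces, was 10.9-fold lower in neurons, or 6.92-fold without barcode set 1. The chaperone gene Hsp90aa1 was 3.32-fold lower in CPM and above 1 per nucleus (log2 0.24). Medians of the remaining lists lay within the central 95%. They were -0.08 for the 6 H3K4 methyltransferases (percentile 60.0), -0.36 for 13 COMPASS subunits, the partners of these enzymes (33.0), and -0.49 for 5 H3K4 demethylases (21.6). They were -0.46 for 24 other chromatin regulators (4.10), -0.77 for 13 cholesterol synthesis genes (6.95) and 0.21 for 16 glycolysis genes (94.0). Members went both ways, such as Chd5 (8.99-fold higher), Tet1 (0.312), the glycolytic enzymes Eno2 (4.59-fold higher) and Aldoc (12.3-fold lower), and Kdm6a (0.311), of which Tet1 and Kdm6a were above 1 per nucleus (log2 0.30 and 0.29). Every list median of this comparison was above 0 per nucleus, where each ratio is 3.94 times as large.

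Among 3056 held-out genes, which took no part in clustering, had at least 500 UMIs and moved in 1 direction in every set, the highest ratios in neurons belonged to Tex50 (72.0, 19.9 to 595, from 2 non-neuronal UMIs), Iqschfp (52.4), Slit3, an axon guidance ligand (46.2, 40.5 to 52.8), Abcc8 (42.0), the ephrin receptor gene Epha6 (34.8), the cation channel gene Trpc7 (31.5), Hs6st3 (30.8) and Zmat4 (30.6). Iqschfp is a readthrough gene that shares its reads with its neighbours, so its value is uncertain. The lowest were Tnni1 (305-fold lower), the glial gap junction gene Gjc3 (291-fold), Galnt5 (228-fold), Fbxw15 (226-fold), Plxnb3 (207-fold), the neuregulin receptor gene Erbb3 (188-fold), Slco2b1 (183-fold) and Prima1 (181-fold). All values of this comparison rest on how clusters were named. An unnamed cluster of 140 nuclei shared Zic1, Prdm16 and Ano1 among its leading genes with a cluster named inhibitory. Its best class by markers was choroid plexus, so it counts as non-neuronal when put in its best class. Moved alone, it gave a plasticity median of 1.78, so falls of neuronal genes under that alternative may come from neurons on the non-neuronal side. The same alternative puts unnamed clusters of 143 and 114 nuclei, with raised oligodendrocyte markers, among excitatory neurons. Only the plasticity median was computed with the cluster of 140 nuclei moved alone, so the source of the other changes was not tested. With unnamed clusters put in their best class, the medians were 1.68 for plasticity genes, 0.19 for immediate early genes, 2.19 for GABA receptor genes and 1.59 for vesicle release genes. Ratios were then 18.3 for Grin2a, 7.04 for Camk2a, 8.10 for Gabra5, 6.19 for Syt1, 5.42 for Unc13a, 5.25 for Chd5, 2.57 for Eno2 and 1.79 for Npas4. Among held-out genes they were 7.48 for Iqschfp, 21.4 for Slit3, 8.995 for Abcc8, 9.64 for Epha6, 3.80 for Trpc7, 12.1 for Hs6st3 and 10.7 for Zmat4, and the lowest genes were 50.7-fold (Fbxw15) to 73.7-fold (Gjc3) lower. Naming with 10 CPM added instead gave 1.78 for plasticity genes, 0.08 for immediate early genes and 1.60 for Npas4, and moved the other neuronal genes likewise. With 1 CPM added, GABA receptor genes were at 2.59, Setd1a at a ratio of 1.86, Iqschfp at 28.8 and Trpc7 at 50.7, and Galnt5, Fbxw15, Slco2b1 and Aldoc were 97.3, 118, 427 and 19.7-fold lower. With thinning, immediate early genes were at 2.73, Chd5 at a ratio of 15.2 and Abcc8 at 26.2, and Erbb3 and Slco2b1 were 124 and 1070-fold lower. Erbb3 and Slco2b1 had only 30 and 38 neuronal UMIs before thinning. Without thinning, immediate early genes of at least 500 UMIs had a median of 2.43. With doublets kept, Tnni1 and Gjc3 were 164 and 177-fold lower. As medians over sets, Npas4 was at 3.31, Iqschfp at 27.7 and Trpc7 at 10.8, and Ddit4 was 6.10-fold lower. Tex50 ranged from 3.87 to 133 over the alternatives other than unscaled means.

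**Figure D3:**
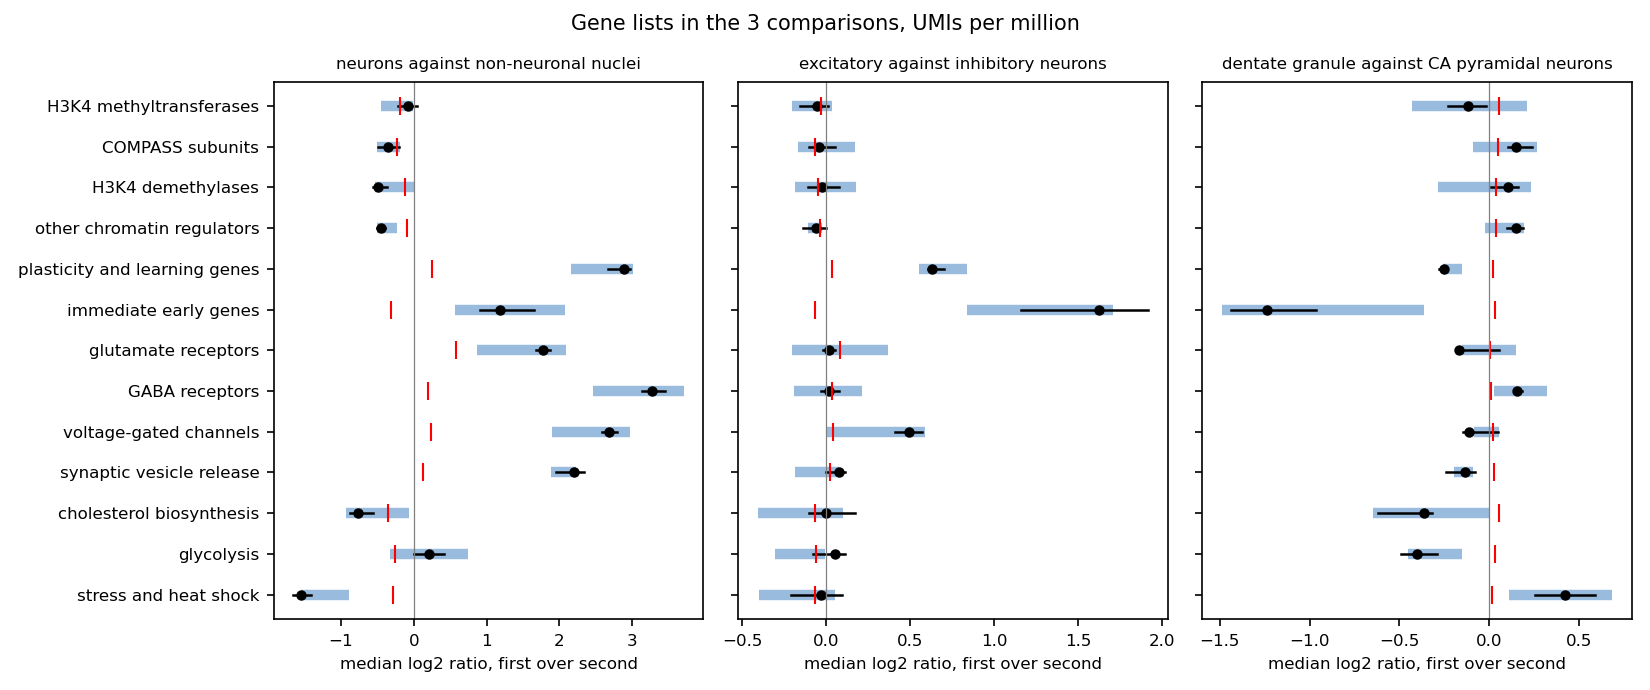
Each panel gives, for 1 comparison, the median log2 ratio of CPM (horizontal axis, first class over second) of 13 gene lists (vertical axis), with black dots for the median, black lines for its 95% counting interval, blue bands for the range over barcode sets and red ticks for the median of random lists. Plasticity genes are at 2.89, 0.63 and -0.25, and immediate early genes at 1.18, 1.62 and -1.24, while on unscaled means per nucleus all medians of the left panel lie above 0.

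The second comparison set 8378 excitatory neurons against 1542 inhibitory neurons, whose mean depths were close (7626 against 7396 UMIs). Setd1b was not separable at this depth, at 17.8 CPM on each side (ratio 0.999, 0.860 to 1.17). Its log2 ratio in single sets ran from -0.38 to 0.22. Kmt2c was slightly higher in excitatory neurons (1.12, 1.08 to 1.17, in 5 of 6 sets) and Kmt2a slightly lower (0.926, 0.890 to 0.963, in 6 of 6 sets). Plasticity and learning genes were higher in excitatory neurons, with a median log2 ratio of 0.63 (percentile 100), and 11 of 37 were at least 2-fold higher. Bdnf, a neurotrophin released with activity, was 22.8-fold higher and its receptor gene Ntrk2 was 2.03-fold lower.

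Kmt2b (0.873, 0.780 to 0.979) and Setd1a (0.831, 0.698 to 0.996) were below 1 by little more than counting error, and with nuclei thinned to 1000 UMIs both lay above it (log2 0.18 and 0.74). After thinning, only 2.67% and 0.650% of 1538 inhibitory neurons had a UMI of Kmt2b and Setd1a. No interval was computed for the thinned ratios, so they do not establish a reversal. Kmt2d was at 1.01 (0.908 to 1.12). Itpka, an inositol phosphate kinase of dendritic spines, was 8.21-fold higher in excitatory neurons, and up to 30.2-fold with 1 CPM added in naming. Gria1, an AMPA receptor subunit, was at a ratio of 0.803. Immediate early genes had a median log2 ratio of 1.62 (percentile 100), with 12 of 17 at least 2-fold higher, such as Nr4a2 (9.37-fold), while Dusp1 was at 0.971. Voltage-gated channel genes were at 0.49 (percentile 99.9), with 7 of 29 at least 2-fold higher and 2 at least 2-fold lower. The T-type calcium channel gene Cacna1h was 6.01-fold higher, and Kcnc2 and Kcnc1, potassium channels of fast-spiking neurons, were 6.22-fold and 4.41-fold lower. Glutamate receptor genes were at 0.02 (percentile 29.6) with members far apart. Of 23, 4 were at least 2-fold higher, such as Grm2 (9.47-fold) and Grik4 (4.59-fold), and 7 at least 2-fold lower, such as Grik1 (36.5-fold) and Gria4 (4.93-fold). GABA receptor genes were also at 0.02 (percentile 45.5), with Gabra5 3.17-fold higher and Gabrg1 7.74-fold lower.

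The other lists lay within the central 95% of random lists in this comparison. Their medians were -0.06 for H3K4 methyltransferases (percentile 43.4), -0.04 for COMPASS subunits (55.6), -0.02 for demethylases (54.9), -0.06 for other chromatin regulators (40.1) and 0.07 for vesicle release genes (65.1). They were -0.00 for cholesterol synthesis (68.9), 0.05 for glycolysis (84.0, although the median was below 0 in each of 6 sets) and -0.03 for stress genes (57.5). Chd3 was 1.44-fold higher and Hdac5 was at 0.609, the vesicle gene Cplx1 was 2.35-fold lower, and Ldha and Ldhb, which encode the subunits of lactate dehydrogenase, went apart (2.10-fold higher and 1.95-fold lower). Ddit3 was 2.80-fold lower.

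Of 2008 held-out genes that qualified, the highest in excitatory neurons were the axon guidance receptor gene Robo3 (74.2, 28.9 to 273), Slc9a4 (44.5), Rtn4rl2 (43.3), Smoc2 (33.3, 22.7 to 51.1), the integrin gene Itga8 (26.4), the hedgehog signal transducer gene Smo (24.8), Nrn1 (22.1) and Vipr1 (21.4). Robo3, Slc9a4 and Rtn4rl2 had 4 UMIs each in inhibitory neurons and Smo had 6, and over the alternatives they ranged from 13.7 to 124, 7.43 to 73.8, 8.41 to 88.2 and 6.83 to 62.5. The lowest were Dlx1, a transcription factor of interneurons (150-fold lower), Kcnmb2 (77.6-fold), the chloride channel gene Ano1 (76.8-fold), Vwc2 (47.8-fold), Pde3a (43.2-fold), Stk32a (41.3-fold), the growth factor receptor gene Egfr (39.6-fold) and Frem1 (32.9-fold). Ano1 led cluster 23, which was named inhibitory on 4 of 15 markers and left unnamed when leading genes were ranked with 1 CPM added, where Ano1 was 10.98-fold lower (9.77-fold at resolution 0.5). With thinning, Bdnf was at a ratio of 11.3, Nr4a2 at 4.85, Grm2 at 5.29, Smoc2 at 22.2, Nrn1 at 45.3 and Dusp1 at 1.47, and Stk32a was 64.2-fold lower. With doublets kept, Smoc2 was at 19.7 and Itga8 at 15.4. Gabrg1 was 3.48-fold lower at resolution 0.5 and 4.89-fold as the median over sets, and Grik1 was 91.6-fold lower with 1 CPM added in naming. The median of immediate early genes was 0.79 both without a filter on nuclei and with clustering centred within sets.

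The third comparison set 2421 dentate granule neurons against 3764 CA pyramidal neurons. Setd1b was not separable at this depth, at 18.1 CPM (16.1 to 20.2) against 17.9 (16.4 to 19.5), a ratio of 1.01 (0.873 to 1.17). Its log2 ratio in single sets ran from -0.61 to 0.43. Kmt2a was lower in granule neurons, at 215 against 256 (ratio 0.838, 0.805 to 0.872, in 6 of 6 sets). Immediate early genes were lower, with a median log2 ratio of -1.24, below all of the random lists (percentile 0), and 9 of 16 were at least 2-fold lower. Arc, a synaptic protein made on activity, was 9.67-fold lower and the nuclear receptor gene Nr4a3 was 10.1-fold lower, while Jun and Btg2 were 4.62-fold and 4.17-fold higher.

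Kmt2d was at 0.825 (0.745 to 0.914) in the pool but below 1 in only 3 of 6 sets. Kmt2c (0.991, 0.953 to 1.03), Kmt2b (0.949, 0.844 to 1.07) and Setd1a (0.897, 0.742 to 1.08) were not separable at this depth. Plasticity and learning genes were lower in granule neurons (median -0.25, percentile 0.77), with 7 of 37 at least 2-fold lower and 1 at least 2-fold higher. Egr1, a transcription factor that is also an immediate early gene, was 5.98-fold lower, or 3.68-fold without set 1, and the adenylyl cyclase gene Adcy1 was 2.87-fold higher. Glycolysis genes (-0.40, percentile 0.14) and cholesterol synthesis genes (-0.36, percentile 0.68) were lower as lists, with 1 of 15 and 1 of 13 at least 2-fold lower. Examples were the phosphofructokinase gene Pfkp (2.18-fold lower), Gpi1 (1.94-fold) and Hmgcs1, an early enzyme of cholesterol synthesis (3.02-fold). Stress genes were at 0.42 (percentile 98.05, and 97.1 with random lists matched on gene length too), with Ddit4 1.97-fold higher and no member of 8 at least 2-fold higher.

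Receptor and channel lists lay within the central 95% of random lists but held members far apart. GABA receptor genes were at 0.15 (percentile 82.8), with Gabrd, a subunit of extrasynaptic receptors, 7.94-fold higher and Gabra3 4.12-fold lower. Glutamate receptor genes were at -0.17 (percentile 10.2, below 0 in 2 of 6 sets), with Grm2 19.3-fold and Grik3 6.97-fold higher. Voltage-gated channel genes were at -0.11 (percentile 10.1), with 4 of 29 at least 2-fold higher and 7 at least 2-fold lower. Kcnc4 was 9.96-fold higher, and the potassium channel genes Kcnq5 and Kcnc2 were 61.5-fold and 61.0-fold lower. Vesicle release genes were at -0.13 (percentile 12.5), with Cplx2 3.04-fold higher and Stx1a 3.14-fold lower. Without scaling, the median of 11897 genes was -0.20 instead of 0.04, Setd1b was at -0.22, and the medians of GABA receptor genes, COMPASS subunits, demethylases and other chromatin regulators were below 0, that of demethylases with thinning too. In CPM, H3K4 methyltransferases were at -0.12 (percentile 19.6), COMPASS subunits at 0.15 (80.4), demethylases at 0.11 (60.8, above 0 in 3 of 6 sets) and other regulators at 0.15 (88.5). Smarca2 and the H3K27 methyltransferase gene Ezh2 were 2.20-fold and 2.07-fold higher, and Hdac4 was 2.49-fold lower.

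Of 1640 held-out genes that qualified, the highest in granule neurons included the matrix gene Npnt (34.1, 25.7 to 46.1), the homeobox gene Mkx (28.2), the synaptic vesicle gene Sv2c (25.6), Zfp536 (22.1), Spata13 (21.5), Slc29a4 (20.7) and the retinol receptor gene Stra6 (17.7). The lowest were Scube1 (83.3-fold lower, and 42.6 to 164-fold over the alternatives), Acss1 (71.6-fold), Cpne8 (64.8-fold), Mgat4c (51.0-fold), Tbata (42.5-fold), St8sia5 (39.9-fold), Pid1 (38.2-fold) and the transcription factor gene Sox5 (37.3-fold). With thinning, Arc, Kcnq5 and St8sia5 were 6.17, 40.9 and 61.5-fold lower, and Sv2c and Spata13 were 16.5 and 50.9-fold higher. At resolution 2, Mkx and Grik3 were 17.2 and 4.502-fold higher, and as medians over sets Acss1 and Egr1 were 47.1 and 2.67-fold lower. Different clusters held these classes in different sets, with granule clusters 6, 0 and 12 and CA1 clusters 24, 3 and 2 holding most of set 1, of sets 2 to 4 and of sets 5 and 6. Summed, immediate early genes were also higher in set 1 than in the other sets. They were at 386 CPM against 201 to 271 in granule neurons and at 939 against 414 to 786 in CA1 neurons. These differences between sets were thus seen on both sides of the comparison, and the ratios above pool them. Set 1 gave 672 of the 2421 granule and 333 of the 3764 CA pyramidal neurons, so it weighs unequally on the sides. By gene, 4 of 7 measured in granule and 10 of 13 in CA1 neurons were higher in set 1 than in sets 2 to 6. In granule neurons their median was at percentile 84.99 of random lists matched on UMIs and gene length.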

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

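Among 75 groups of 5 to 7 barcode sets, Dixon's test found 5 with 1 set far from the others, where chance gives about 1 in 20 groups. All patterns weighed here were seen before their tests were written. After the first values were seen, the rules of 5 tests were changed so that an outcome in favour became an undecided one (marker counts in set 6, a sort, hypothalamus genes, free RNA, ribosomal protein genes in granule neurons), and 9 tests were added (2 on depth in sets 6 and 7, 2 on depth against sets 2 to 4, oligodendrocyte markers in set 6, free RNA without Agrp, and 3 on CA1 neurons). Some region genes, such as Tac1 and Cartpt, had already been seen to lead the cluster they were used on. The labels give 1 group, so no biological explanation was tested for any pattern.

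Set 7 was far from the others in Cajal-Retzius cells (5.88% of nuclei against 0 to 0.853%) and in oligodendrocyte precursors (13.7% against 0 to 2.53%). It held almost no other neurons, while set 6 held almost no nuclei other than neurons. Among non-neuronal nuclei alone, precursors were 91 of 469 in set 7 and 56 of 244 in set 5. On that base set 7 was not the highest. Low depth was argued against, since set 5, of similar depth to set 6, kept 11.0307% non-neuronal nuclei, and neurons held 3.54 to 5.59 times the UMIs of other nuclei in sets 1 to 5, so a minimum of UMIs would remove them last from set 7. Hidden excitatory or inhibitory neurons found little support in set 7, with 0.452% of nuclei richer in their markers, a count that leaves out Cajal-Retzius markers. Hidden oligodendrocytes found little in set 6, with their markers at 0.567% of their level in named oligodendrocytes, while the marker count in set 6 (20.6%) could not tell, as 25.3% of 3827 named excitatory neurons of sets 2 to 4 met the same rule. The marker count can thus miss some neurons in set 7 too, where barcodes were shallower (median 1012 UMIs). A sort that parted neurons from other nuclei before loading stays open, since the excitatory markers in oligodendrocytes of set 7 (66.3 CPM, 43.7 to 96.4, against 149 to 189 in sets 1 to 5) would be low with few neurons for any reason, and the labels give only the 7AAD sort.

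An unnamed cluster of 722 nuclei, 705 of them in set 1 (23.9% of that set), was a signal in nuclei that no comparison used, and its leading genes included Baiap3, Resp18, Scg2, Dlk1, Tac1, Cartpt and Sim1. Tissue from a neighbouring region was tested with genes of 4 regions, of which 56.25% for hypothalamus (9 of 16) were at least 4-fold above hippocampal neurons, against 54.5% for striatum, 50% for thalamus and 44.4% for septum, so the region could not be told. Pairs of nuclei in 1 droplet were argued against by a median of 6962 UMIs. It was 0.912 of that in named neurons of set 1 (7630, ratio interval 0.863 to 0.981). The median doublet score was nevertheless higher than in those neurons (0.0446 against 0.0337, and 0.350 in called doublets of set 1). Free RNA could not be told, since hypothalamus genes in granule neurons of set 1 reached 68.2% of their level in the cluster, a value that rests on Agrp, and 26.6% without it.

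Summed, immediate early genes were higher in granule and CA1 neurons of set 1 than in other sets. The pattern was seen first from Arc, Egr1 and Egr4 leading a CA1 cluster. By gene, 4 of 7 measured in granule and 10 of 13 in CA1 neurons were higher in set 1 than in sets 2 to 6. The sum in oligodendrocytes of set 1 was the highest too (166 CPM, 142 to 194, against 88.4 to 132). Depth could not be told, since levels in CPM are already scaled and random thinning leaves their expected value nearly unchanged. After thinning, set 1 was compared with the highest of sets 2 to 4, whose nuclei are deeper. It was 1.42 times as high in granule (1.14 to 1.76) and 1.72 times in CA1 neurons (1.36 to 2.17). Against the shallower set 5, full counts gave 386 CPM in granule neurons (368 to 405) against 236 (161 to 333). In CA1 neurons they gave 939 (899 to 980) against 786 (749 to 824). With thinning the granule values were 378 (333 to 427) and 345 from 19 UMIs, and the CA1 values 855 (736 to 988) and 751. Residual cytoplasm stays open, since ribosomal protein genes were higher in set 1 by a median log2 ratio of 1.43 in CA1 neurons (matched random lists 0.58, immediate early genes 0.96) and 2.47 in oligodendrocytes (random 0.95), while in granule neurons (1.93) random lists (0.90) alone exceeded the immediate early genes (0.78), so that value could not tell. Gene length and level could account for the granule value (percentile 84.99 among random lists matched on both). The CA1 value (percentile 99.95) could not tell, since the list holds Arc, Egr1 and Egr4, from which the pattern was first seen. There Egr4 was 8.47-fold, Arc 7.20-fold and Egr1 5.92-fold higher.

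In neurons against non-neuronal nuclei, set 5 was far from the others in the median log2 ratio of glutamate receptor genes (0.87 against 1.88 to 2.09). Its non-neuronal side was small and shallow, with 244 nuclei of a mean of 885 UMIs, against means of 1639 to 2550 in sets 1 to 4. The floor used where a side had no UMI can understate ratios of neuronal genes at so few UMIs. Whether depth or this floor gave the low median of set 5 was not tested. In the same comparison, set 1 was far from the others in that of glycolysis genes (-0.33 against 0.48 to 0.74). In excitatory against inhibitory neurons, set 5 was far from the others in that of voltage-gated channel genes (-0.00122 against 0.41 to 0.59).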

How the results depend on the processing

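Every alternative fixed beforehand was run, and those on naming, best class, the median over sets, gene length and held-out genes were chosen after the data were seen. Ratios were not tested across barcode sets, which no label ties to samples, and enter as medians over sets and counts of direction. Leaving aside unscaled means, 3489 of 4020 gene ratios stayed within the counting interval, 526 moved and 5 reversed, and 64 (these included) changed sign. Of 926 list medians 804 stayed and 122 moved, and 49 changed sign, all of lists within the central 95% of random lists. Of 306 shares of nuclei 171 stayed and 135 moved. Of 39 list percentiles with gene length matched too, 38 kept their side and 1 weakened. Depth limits Setd1b, with 176 UMIs in non-neuronal nuclei, and genes with few UMIs on 1 side.

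Unscaled means per nucleus turned these log2 ratios of neurons against non-neuronal nuclei, by construction, as neurons held 3.94 times the UMIs: Kmt2c 1.22, Setd1b 1.40, Dpy30 1.15, Kdm6a 0.29, Kdm5a 1.47, Kdm1b 1.19, Ezh2 0.68, Tet1 0.30, Cdk5 1.08, Creb1 0.83, Jun 1.13, Gabrg1 1.56, Gabbr1 1.28, Hcn2 0.70, Sv2a 1.42, Vamp2 1.14, Idi1 0.64, Msmo1 0.33, Pkm 0.81, Hsph1 1.41, Dnajb1 1.29, Hsp90aa1 0.24 and the stress list 0.43. They moved the plasticity median to 4.87, and in granule against CA neurons to -0.48, with Setd1b at -0.22, Kdm5c at -0.0144 and Kdm5a at -0.10. Thinning put Setd1b at -0.32 in neurons, Kmt2b at 0.18 and Setd1a at 0.74 in excitatory neurons, and Kdm5c at -0.00342 in granule neurons.

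Naming with 1 CPM added gave plasticity medians of 2.45 in neurons and 0.76 in excitatory neurons, and 10 CPM gave 1.78 and Kdm5b -0.0146. Unnamed clusters in their best class gave 1.68. Moving only the unnamed cluster of 140 nuclei, whose best class by markers was choroid plexus, gave 1.78291, and moving all others gave 2.97. That cluster thus accounts for most of this fall. It shared leading genes with a cluster named inhibitory, so its place on the non-neuronal side is uncertain. In excitatory neurons the plasticity median was 0.53 without a filter, 0.72 at resolution 0.5 and 0.52 with centred features. In granule neurons it was -0.39 with nuclei weighted equally, -0.30 at resolution 2 and -0.20 as the median over sets. Leaving out 1 set gave 2.84 to 2.99, 0.62 to 0.71 and -0.29 to -0.25 in the 3 comparisons, Setd1b at -0.60 to -0.48, -0.11 to 0.05 and -0.13 to 0.09, and Gabrg1 in neurons at -0.83 (without set 2) to 0.15 (without set 1). Neurons were 68.8% of nuclei with at least 1000 UMIs, 63.9% with doublets kept, 61.7% at resolution 0.5, 59.8% with naming at 1 CPM, 61.8% at 10 and at 20 CPM, 68.0477% with best classes, 58.8 to 71.3% leaving out 1 set, and 67.9805% as the median over sets. In the best-class share, the unnamed cluster of 722 nuclei counted on neither side, as its best class was neuroblast. That of 140 nuclei counted as non-neuronal. Unnamed clusters of 143 and 114 nuclei, with raised oligodendrocyte markers, counted as neurons. Apart from unscaled means and the fall of the plasticity median with best classes, the cause of these changes was not tested.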

Other observations

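Genes of the Y chromosome were transcribed in all 7 barcode sets. Uty was at 111 to 161 CPM, Ddx3y at 36.2 to 92.8, Eif2s3y at 73.6 to 99.1 and Kdm5d at 37.6 to 61.7. Of 6 sex-linked genes, 4 were measured, with median log2 ratios of -0.39 in neurons against non-neuronal nuclei, -0.25 in excitatory against inhibitory neurons and 0.09 in granule against CA neurons. Of 4 haemoglobin genes, 0 reached the minimum of 100 UMIs. Setd1b in Cajal-Retzius cells was at 47.2 CPM (22.6 to 86.7, from 10 UMIs).

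Some unnamed clusters had leading genes of their own. A cluster of 158 nuclei, with none in sets 1, 6 and 7, was led by Dcn, Fbln2 and Gpc3, a cluster of 84 nuclei by Ebf1, Lef1 and Syt9, and a cluster of 36 nuclei by Ebf2, Ebf3 and Sema3a. An unnamed cluster of 140 nuclei, all in set 1, and the cluster of 229 nuclei named inhibitory shared Zic1, Prdm16 and Ano1 among their leading genes.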
